A study of Arabidopsis thaliana with 6 samples.

How the data were processed

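Total RNA of 7-day Arabidopsis thaliana seedlings was sequenced in 6 libraries, 3 from the wild-type accession Col and 3 from the mutant tsk-4, which carries a mutant allele of TONSOKU (TSK). Per the labels' protocols the RNA was taken up with a Minibest plant RNA kit and the libraries were made with a NEBNext Ultra RNA kit. Genotypes and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

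The authors deposited 3 tables of TPM, for genes, for transposable element (TE) genes and for annotated TE fragments. Per the submitters' processing notes the tools included fastp 0.20.1, HISAT2, HTSeq 0.11.2 and DESeq2 1.26.0, with the build TAIR10. The role and settings of each tool, the use of strand and the treatment of reads that map to several places are not given in the sources used here. TE copies and near-identical genes therefore carry an open uncertainty. In each deposited TPM table every library summed to 1000000, so the tables were normalized separately and tests were made within a table. The gene table had 33189 rows, of which 33056 matched the reference annotation (TAIR10.1) by identifier, and all 3901 TE genes matched. Coordinates are 1-based and come from that annotation. Coordinates and families of TE fragments were not used here. Only 50 of the 3901 TE genes carry a descriptive note in the reference, so the planned comparison of TE superfamilies is not analysed here.

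The TPM used the full genomic span of a gene, introns included, as its length. Multiplied by that span and by 1 constant per library, the values above 0 came out as whole numbers of reads within 0.02 reads, for 100% of them in the gene table and for 99.76% in the library of the TE gene table where the share was lowest. The gene table held 13726929, 14934533 and 14523771 reads in Col 1, 2 and 3 and 14946295, 14418394 and 14884988 in tsk-4 1, 2 and 3. The TE gene table held 20505, 21628 and 20595 reads in Col and 24356, 21413 and 24565 in tsk-4. Lengths of TE fragments were inferred from the steps of the values themselves, with no annotation to check them, and gave 157608 to 168042 reads per library. The smallest length that gave whole reads in all libraries was taken. Read numbers of fragments are therefore the smallest that the values allow, and may be too low. In 1 kb, 1 read was worth 0.149 to 0.164 TPM in the gene table, 99.6 to 123 TPM in the TE gene table and 1.29 to 1.37 TPM in the fragment table. The filter and the pseudocount below thus lie far under 1 read in the TE gene table. Intervals and floors given with read numbers cover counting error only.

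The main test, fixed before the data were examined like the gene lists and the alternatives unless stated otherwise, was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(TPM + 0.5). Features with at least 1 TPM in at least 3 of the 6 libraries were tested, p-values were adjusted by the Benjamini-Hochberg method within a table, and a call needed an adjusted p under 0.05. Log2 changes are tsk-4 over Col on the log2(TPM + 0.5) scale, which understates changes of low genes, with standard errors from limma; means carry the SD over 3 libraries. Gene lists with at least 3 tested members, 15 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists. They were tested again with an estimated correlation and with fry. fry asks whether the members of a list move 1 way without comparing them with other genes. It was run only on TPM as deposited, where the median log2 change of tested genes was 0.083, so it leans upward. A second test, chosen after seeing the data, was limma-voom on the recovered reads, with library sizes from the gene table times median-ratio factors and at least 10 reads over the 6 libraries. A sum of TPM over TEs is fixed by the separate normalization, so reads on TEs per 1000000 reads of the gene table took the place of the planned share of TPM. TE gene positions were compared with a two-sided Fisher exact test, using approximate centromere positions of the build that were set by hand and are not in the annotation. The filter decides which TE genes silent in Col are tested, so the comparison was also made over all annotated TE genes and other sets, chosen after the result was seen. Values per library were compared with a two-sided exact permutation test, which cannot go below p = 0.1 with 3 libraries against 3. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

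Genes were named by this rule: TSK; from each list the 2 to 4 called members with the smallest adjusted p, or the 2 with the highest mean TPM where none was called; and the called features with the largest changes whose 3 tsk-4 libraries all lay on 1 side of the Col libraries, 8 higher and 8 lower genes, 6 and 4 TE genes and 5 and 3 TE fragments. SOG1, LHCA3, LHCB6, RBCS1A, AT3G46345, SADHU3-2 and the SAUR and KCS families were chosen after their values were seen. Of what was picked in these ways 1 gene, still included in the counts, and 1 family are not reported here. The lists were DNA damage response, G2/M cell cycle, DNA replication, replication-coupled histone H3.1, DNA methylation and heterochromatin, Polycomb repressive complex 2 (PRC2), H3K27me3-regulated developmental genes, meristem, loci silenced by DNA methylation, photosynthetic, root, seed and pollen markers, heat stress, salicylic acid and defence, abscisic acid and cold, and anthocyanin.

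Both tests were tried on simulated reads with known changes, drawn with 1 dispersion for all tables, taken from genes with many reads. The baseline of each feature was its mean over all 6 libraries, so TE genes silent in Col were given reads in Col. The rates below therefore do not describe calls on TEs with reads in tsk-4 alone. Among 19474 simulated genes the TPM test recovered 92.9% of 2-fold and 98.0% of 4-fold changes and called 15 unchanged genes. Among 720 simulated TE genes it recovered 23.8% of 63 changed 2-fold and 46.7% of 60 changed 4-fold, and called 17 unchanged ones. The test on reads, run on 359 TE genes, recovered 43.5% of 46 and 65.3% of 49 and called 2. Among 2731 simulated TE fragments the TPM test recovered 20.8% and 39.4% and called 22 unchanged ones; the test on reads, run on 2122, recovered 42.7% and 77.4% and called 3. Results of both tests are therefore given for TEs.

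Alternatives were pseudocounts of 1 and 0.1, no filter on low values, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, a replicate block, no mean-variance trend, a 2-fold minimum, windows of 2 and 5 Mb around the centromeres, sums without the 5 most abundant elements, and leaving out each library in turn. The last applied the filter again to the 5 remaining libraries; after those counts were seen it was also run on the features of the full test, which is the version used for single genes. Replicates were compared before averaging: the chi-square per degree of freedom of their gene reads was 2.43 to 7.42 within a genotype, so no library was treated as a repeat of another.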

Results

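The series asked how TONSOKU, a nuclear protein that acts in DNA repair during replication, bears on repressive chromatin in Arabidopsis, and this part compared the transcriptome of the mutant tsk-4 with that of Col. RNA-seq of 7-day seedlings gave 3 libraries per genotype with 13726929 to 14946295 reads in the gene table. The first principal component of the tested genes held 52.5% of the variance and separated the genotypes.

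The mutated gene itself was lower in the mutant. TSK (AT3G18730, chromosome 3, 6445852 to 6453201) measured 3.62 ± 0.234 in Col and 0.903 ± 0.0657 TPM in tsk-4 (SD, n = 3 each), a log2 change of -1.55 ± 0.20 (limma adjusted p = 0.00097). The Col libraries held 167, 165 and 181 reads of the gene and the tsk-4 libraries 40, 45 and 44. The labels do not say which part of the gene tsk-4 alters, so the value checks the labels over the whole gene only.

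**Figure D1:**
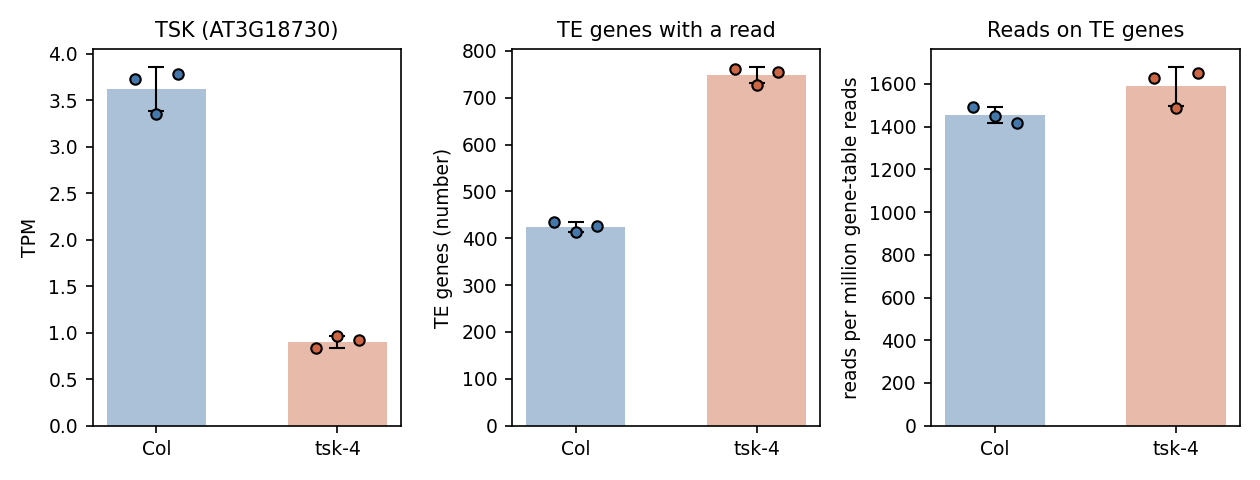
TSK level in TPM, number of TE genes with at least 1 recovered read, and reads on TE genes per 1000000 reads of the gene table, for Col and tsk-4; points are libraries, bars the mean and whiskers the SD (n = 3). TSK is lower and the number of TE genes with a read higher in every tsk-4 library than in every Col library, with 728 to 761 against 413 to 434 TE genes, while the reads on TE genes overlap.

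The genes with the largest rises were nearly silent in Col. AT3G46340 (chromosome 3, 17026658 to 17031897), a protein-coding gene, went from 2 reads in Col to 1612 in tsk-4, a ratio of 750.4 (95% counting interval 207 to 6202), and reached 15.8 ± 1.39 TPM (SD, n = 3). PR2 (BGL2 in the annotation; AT3G57260, chromosome 3, 21188397 to 21189967), a pathogenesis-related beta-glucanase, went from 1 to 305 reads, a ratio of 284 (interval 50.6 to 11252). The miscellaneous RNA AT4G09215 had 0 reads in Col and 81 in tsk-4, at least 25.9-fold higher against a floor of 3 reads over the group. HAK5 (AT4G13420, chromosome 4, 7796782 to 7802251), a high-affinity potassium transporter, rose from 0.606 ± 0.473 to 15.8 ± 1.28 TPM, a log2 change of 3.97 ± 0.29 (limma adjusted p = 4.6e-05). AT3G13130, NUDT24 (AT5G19470), a Nudix hydrolase, LURP1 (AT2G14560), a gene of pathogen defence, and the long non-coding RNA AT3G06955 rose by log2 changes of 4.09, 3.69, 3.40 and 3.30.

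Of the 8 largest falls 4 were microRNA genes with few reads. MIR3440b fell from 14 to 1 reads, a ratio of 15.0 (95% counting interval 2.29 to 636). MIR394b fell from 20 to 2, a ratio of 10.7 (interval 2.61 to 94.8), and MIR169k from 39 to 8. MIR864 went from 5 to 0 reads, 1.71-fold lower against a floor of 3 reads over the group, too few reads to bound the fall. AGP30 (AT2G33790, chromosome 2, 14293561 to 14295353), an arabinogalactan protein of the cell wall, fell from 12.1 ± 2.102 to 2.35 ± 0.692 TPM (limma adjusted p = 0.00022). AT1G14250 fell from 15.6 ± 1.21 to 3.68 ± 0.395 TPM (adjusted p = 2.2e-05), AT3G55710 from 8.24 ± 1.44 to 1.71 ± 0.488 TPM and AT2G33830 from 12.01 ± 7.45 to 1.82 ± 1.06 TPM. On recovered reads MIR394b was not called (limma-voom adjusted p = 0.068) and MIR864 had too few reads to be tested.

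Of 19574 genes tested, limma called 2912 higher and 971 lower in tsk-4, 75.0% of the calls being higher, and 445 and 121 changed at least 2-fold. The split depended on the scaling: median-ratio scaling gave 1802 higher and 1607 lower (52.9% higher), quantile normalization 1704 and 1660 (50.7%) and recovered reads 2093 and 1954 (51.7%). Of the calls on TPM, 1978 higher and 935 lower genes were also called on reads. Without Col 2 the test on reads gave 1389 higher and 1189 lower, and without tsk-4 3 1222 lower. With the filter applied again to 5 libraries, higher calls fell to 1802, 1927 and 1783 without Col 2, tsk-4 1 and tsk-4 3, and lower calls to 558, 501, 626 and 578 without Col 1, Col 2, tsk-4 2 and tsk-4 3. The genotypes did not overlap for 37.5% of tested genes, where chance gives 10%.

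DNA damage response genes rose in part. Of 21 tested members 13 rose and 0 fell (14 rose adjusted over the list alone), with a median log2 change of 0.73. TSO2 (AT3G27060), a ribonucleotide reductase subunit, went from 134 ± 11.7 to 282 ± 1.03 TPM and PARP2 (AT4G02390), a poly(ADP-ribose) polymerase, from 3.76 ± 0.365 to 12.4 ± 1.02 TPM. NAC044 (AT3G01600), a transcription factor of the damage checkpoint, rose from 0.693 ± 0.272 to 7.43 ± 0.572 TPM (limma adjusted p = 6.5e-05). SOG1, the main regulator of the damage response, had a log2 change of -0.08 and was not called (adjusted p = 0.65). camera gave the list an adjusted p of 1.5e-07, which was lost with an estimated correlation (adjusted p = 0.46), and the fry adjusted p was 0.0039. TSO2 overlaps an annotated gene on its own strand, so its reads are uncertain.

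Genes of the G2/M phase rose in part: 8 of 22 tested members rose and 0 fell (10 rose adjusted over the list alone), with a median log2 change of 0.34. HINKEL (AT1G18370), a kinesin of cytokinesis, went from 21.5 ± 3.05 to 51.2 ± 3.43 TPM, CYCB1;2 (AT5G06150), a mitotic cyclin, from 33.0 ± 3.66 to 65.1 ± 2.88 TPM, and CYCA1;1 and CDKB2;2 rose by log2 changes of 0.44 and 0.56. The camera adjusted p was 0.0080 (adjusted p = 0.76 with an estimated correlation) and became 0.075 without Col 1, and the fry adjusted p was 0.078. With median-ratio scaling 4 of the 22 rose, and CDKB2;2 overlaps a gene on the other strand.

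No shared direction was detected among replication genes. Of 19 tested 1 rose, POL2A (AT1G08260), the catalytic subunit of DNA polymerase epsilon, from 5.01 ± 0.0607 to 6.79 ± 0.536 TPM (limma adjusted p = 0.049), and 0 fell; 0 were called adjusted over the list alone, the median log2 change was 0.00 and the camera adjusted p 0.52, while fry for changes in either direction gave an unadjusted p of 0.00051. With median-ratio scaling 0 rose, on recovered reads 1 rose and 1 fell, and POL2A overlaps genes on the other strand. Of 5 replication-coupled histone H3.1 genes HTR1 and HTR2 rose, by 0.23 and 0.33 (2 adjusted over the list alone, camera adjusted p = 0.25, or 0.020 without Col 3). Neither was called on recovered reads (limma-voom adjusted p = 0.17 and 0.073), and the near-identical H3.1 genes can share reads.

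**Figure D2:**
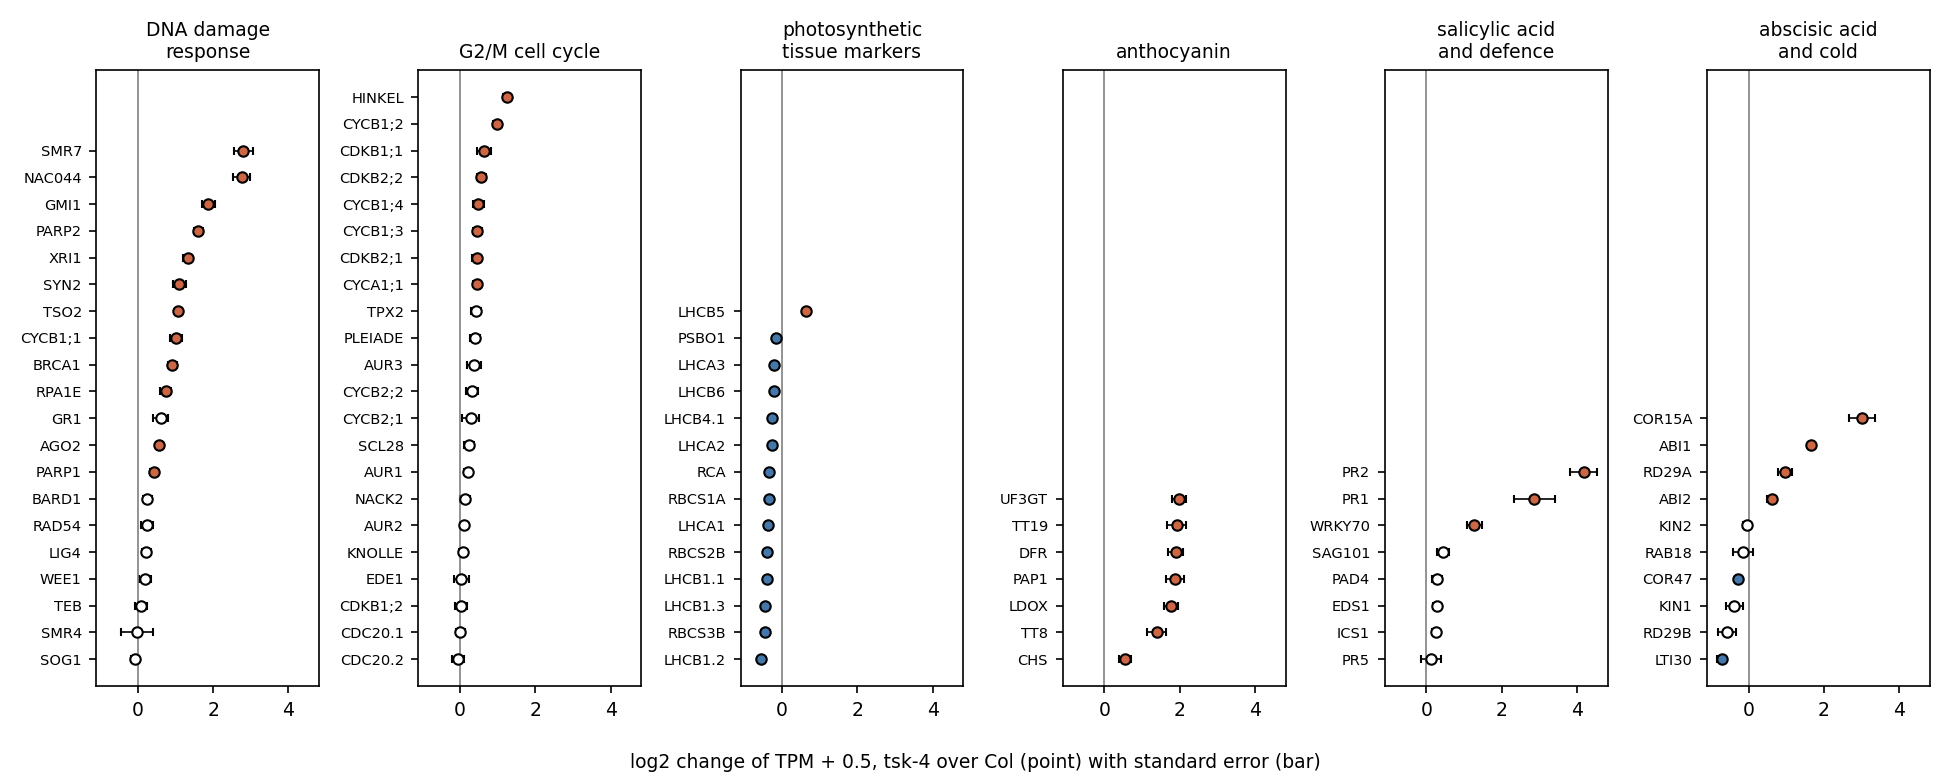
Log2 change of TPM + 0.5, tsk-4 over Col, for tested members of 6 gene lists (points, n = 3 libraries per genotype) with the standard error from limma (bars). Orange points rose, blue points fell and white points were not called. Of the anthocyanin genes 7 of 7 rose, and 13 of 14 photosynthetic genes fell. With quantile normalization, which sets the highest values equal in every library, 5 of 14 fell and LHCA3, LHCB6 and RBCS1A turned upward.

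Chromatin genes moved in both directions. Of 31 tested genes of DNA methylation and heterochromatin 7 rose and 2 fell, in the same numbers adjusted over the list alone, and with median-ratio scaling 3 rose and 3 fell, with quantile normalization 1 and 3 and on recovered reads 6 and 4. CMT2 (AT4G19020), a chromomethylase acting on TEs, fell from 20.9 ± 0.822 to 14.7 ± 0.995 TPM and ROS1 (AT2G36490), a DNA demethylase, from 20.22 ± 1.34 to 12.1 ± 2.49 TPM (limma adjusted p = 0.0054 and 0.0074). The linker histone genes H1.2 and H1.1 rose by 0.28 and 0.37, and both overlap genes on the other strand. The camera adjusted p was 0.54. Of 10 genes of PRC2 and its associated factors VRN2 (AT4G16845), a core subunit, rose from 12.7 ± 0.724 to 17.44 ± 0.655 TPM and 0 fell, or 1 with quantile normalization and 1 on recovered reads (1 rose adjusted over the list alone, camera adjusted p = 0.54).

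Of 23 developmental genes regulated by H3K27me3, the mark set by PRC2, 7 were expressed enough to be tested. KNAT6, STM and KNAT1, homeobox genes of the shoot meristem, rose by 0.56, 0.78 and 0.37 and 0 fell (5 rose adjusted over the list alone); the camera adjusted p was 0.30 and the fry adjusted p 0.013. KNAT1 was not called on recovered reads (limma-voom adjusted p = 0.069). In the meristem list 3 of 8 rose and 0 fell (3 rose adjusted over the list alone): SHR (AT4G37650), a regulator of root patterning, from 22.5 ± 2.53 to 34.8 ± 3.08 TPM, and ANT and CUC3 by 0.36 and 0.80 (camera adjusted p = 0.33, fry adjusted p = 0.0097).

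Of 6 loci chosen as examples of silencing by DNA methylation only QQS and EVD could be tested, and neither showed a detected change. SDC and FWA did not pass the filter of the gene table. QQS (AT3G30720), the 1 member that passed the filter of the gene table, measured 4.78 ± 0.507 in Col and 5.16 ± 1.40 TPM in tsk-4 (limma adjusted p = 0.82, unadjusted p = 0.70; limma-voom adjusted p = 0.98). In the TE gene table EVD (AT5G17125), a Copia retrotransposon, had 16 reads in Col and 14 in tsk-4 (limma adjusted p = 0.79), CAC1 (AT2G12210) 0 and 1, and MU1 (AT4G08680) 0 and 0. For CAC1 and MU1 a difference was not detectable at this depth.

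Photosynthetic genes mostly fell. Of 14 photosynthetic markers 13 fell and 1 rose, in the same numbers adjusted over the list alone. The light-harvesting genes LHCB1.2 (AT1G29910) and LHCB1.1 (AT1G29920) fell by 0.57 and 0.40 on the log2 scale and the Rubisco small subunit gene RBCS3B (AT5G38410) fell by 0.47, while LHCB5 (AT4G10340) rose from 6207 ± 178 to 9670.1 ± 306 TPM. The 14 genes together made up 14.3 ± 0.206% of the gene TPM in Col and 11.4 ± 0.212% in tsk-4 (SD, n = 3; exact permutation p = 0.1, the smallest possible). camera gave an adjusted p of 4.2e-10 (adjusted p = 0.46 with an estimated correlation). With median-ratio scaling and on recovered reads 13 fell and 1 rose. With quantile normalization 5 fell, LHCA3, LHCB6 and RBCS1A turned upward and the camera adjusted p was 0.093. This method sets the highest values equal in every library, so it removes much of a joint fall of abundant genes by construction. The LHCB1 and RBCS genes have near-identical copies that can share reads.

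All 7 tested anthocyanin genes rose (7 adjusted over the list alone, 6 with median-ratio scaling), with a median log2 change of 1.88. UF3GT (AT5G54060), a glycosyltransferase, rose from 14.8 ± 0.853 to 62.4 ± 20.6 TPM, DFR (AT5G42800) from 60.3 ± 15.6 to 226 ± 60.6 TPM, LDOX (AT4G22880) from 66.6 ± 15.9 to 229.8 ± 62.0 TPM and their regulator PAP1 (AT1G56650) from 4.32 ± 1.47 to 17.2 ± 5.12 TPM. The camera adjusted p was 1.0e-05 (adjusted p = 0.63 with an estimated correlation) and the fry adjusted p 0.013.

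Of 8 salicylic acid and defence genes 3 rose and 0 fell (5 rose adjusted over the list alone). Besides PR2 these were WRKY70 (AT3G56400), a defence transcription factor, from 5.64 ± 1.51 to 14.3 ± 2.87 TPM, and PR1 (AT2G14610), whose tsk-4 libraries spread from 2.03 to 14.1 TPM against a Col mean of 0.344 ± 0.164 TPM. The camera adjusted p was 0.0088 (adjusted p = 0.68 with an estimated correlation). Of 10 abscisic acid and cold genes 4 rose and 2 fell, in the same numbers adjusted over the list alone, and 3 fell on recovered reads. ABI1 (AT4G26080), a phosphatase that restrains abscisic acid signalling, rose from 54.9 ± 1.14 to 174 ± 4.12 TPM, COR15A (AT2G42540), a cold-induced chloroplast protein, from 2.24 ± 1.23 to 20.4 ± 5.53 TPM and RD29A (AT5G52310) from 26.4 ± 4.09 to 53.0 ± 14.7 TPM, while the dehydrin LTI30 (AT3G50970) fell from 61.1 ± 3.43 to 37.3 ± 6.63 TPM. The median log2 change was -0.10 while the mean was 0.41, and camera gave an adjusted p of 0.95 in the upward direction and fry 0.013. ABI1 overlaps a gene on the other strand.

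Few markers of other tissues or of heat stress were called. Of 10 root markers PRP3 rose from 58.4 ± 0.194 to 79.5 ± 8.45 TPM and EXPA18, which overlaps a gene on the other strand, from 12.03 ± 1.44 to 17.61 ± 0.318 TPM (2 adjusted over the list alone; 0 fell, but 2 with median-ratio scaling, 2 with quantile normalization and 1 on recovered reads; camera adjusted p = 0.86). Of 6 seed markers 0 were called by limma, also adjusted over the list alone, 0 had an unadjusted p under 0.05 and 0 rose and 0 fell on reads; CRA1 measured 58.0 ± 34.5 in Col and 56.8 ± 27.01 TPM in tsk-4 and EM6 13.6 ± 2.71 and 10.6 ± 1.11 TPM (camera adjusted p = 0.52, downward, while the median was 0.01 and the mean 0.13). Of 6 pollen markers 0 passed the filter. Of 5 heat stress genes 0 were called by limma over all genes (1 had an unadjusted p under 0.05, and 0 rose and 0 fell on reads) and 1 adjusted over the list alone; HSP70-4 measured 80.5 ± 17.9 and 104 ± 19.0 TPM and HSP90.1 14.4 ± 3.72 and 16.6 ± 3.73 TPM in Col and tsk-4 (median log2 change of the list 0.38, camera adjusted p = 0.52).

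Many TE genes had reads in tsk-4 and none in Col. On average 424 ± 10.6 TE genes had at least 1 read in a Col library and 748 ± 17.39 in a tsk-4 library (SD, n = 3; exact permutation p = 0.1, the smallest possible). AT2G06720 (chromosome 2, 2678827 to 2681289) had 0 reads in Col and 120 in tsk-4, at least 38.7-fold higher against a floor of 3 reads over the group. AT5G44925 (chromosome 5, 18142274 to 18146632) had 0 and 106 reads, at least 34.0-fold higher, and AT1G42050 (chromosome 1, 15707077 to 15710285) 0 and 90, at least 28.9-fold higher. AT3G46487, AT3G43863 and AT2G10285 had 0 reads in Col and 62, 23 and 16 in tsk-4. AT4G28900 (chromosome 4, 14259141 to 14263704) fell from 250 to 92 reads and AT4G02312 from 20 to 6, while AT3G33377 and AT3G33575 had 4 and 3 reads in Col and 0 in tsk-4.

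Of 543 TE genes tested, limma called 128 higher and 16 lower, 12 of the 16 by less than 2-fold. In the TE table rescaled to the gene table, a version chosen after the results were seen, it called 133 higher and 6 lower. Of the 128, 113 had 0 reads in Col. Over all 128 the median was 11 reads over the 3 tsk-4 libraries, and 51 had under 10. All 113 TE genes with reads in every tsk-4 library and none in Col were called higher. The filter admits no other TE genes silent in Col, so for the 113 the call only restates this pattern of detection. Recovered reads gave 103 higher and 11 lower of 345, of which 76 and 8 were also calls on TPM. Quantile normalization moved the median log2 change of tested TE genes from 0.60 to -0.26 and gave 57 higher and 36 lower (61.3% higher, against 88.9%). That method gives every library the same distribution, while 113 of the tested TE genes had reads in tsk-4 alone. By construction it therefore lowers other TE genes in tsk-4. Median-ratio scaling gave 124 higher and 20 lower. With 1 tsk-4 library left out and the filter applied again, limma called 0, 3 and 0 TE genes higher without tsk-4 1, 2 and 3. At an unadjusted p under 0.05 in either direction there were 54, 53 and 56. Of the 128, 113 then fail the filter, and without tsk-4 1 or 3 the rest were tested but lost their call. limma called 0, 1 and 0 lower in the same order, and 8 without Col 2. On the features of the full test, a version added after those counts were seen, it called 120, 118 and 117. The test on reads called 41, 44 and 52 higher without Col 1, 2 and 3 and 67, 78 and 63 without tsk-4 1, 2 and 3, with 5, 3, 6, 5, 4 and 7 lower in the same order.

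The summed level of TE genes was not shown to differ. Reads on TE genes were 1453 ± 38.1 per 1000000 reads of the gene table in Col and 1588 ± 90.0 in tsk-4 (SD, n = 3; exact permutation p = 0.2), and 965 ± 22.6 and 1101 ± 55.6 without the 5 most abundant TE genes (exact permutation p = 0.1, the smallest possible). These levels are set across tables that were normalized separately, through their recovered reads.

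**Figure D3:**
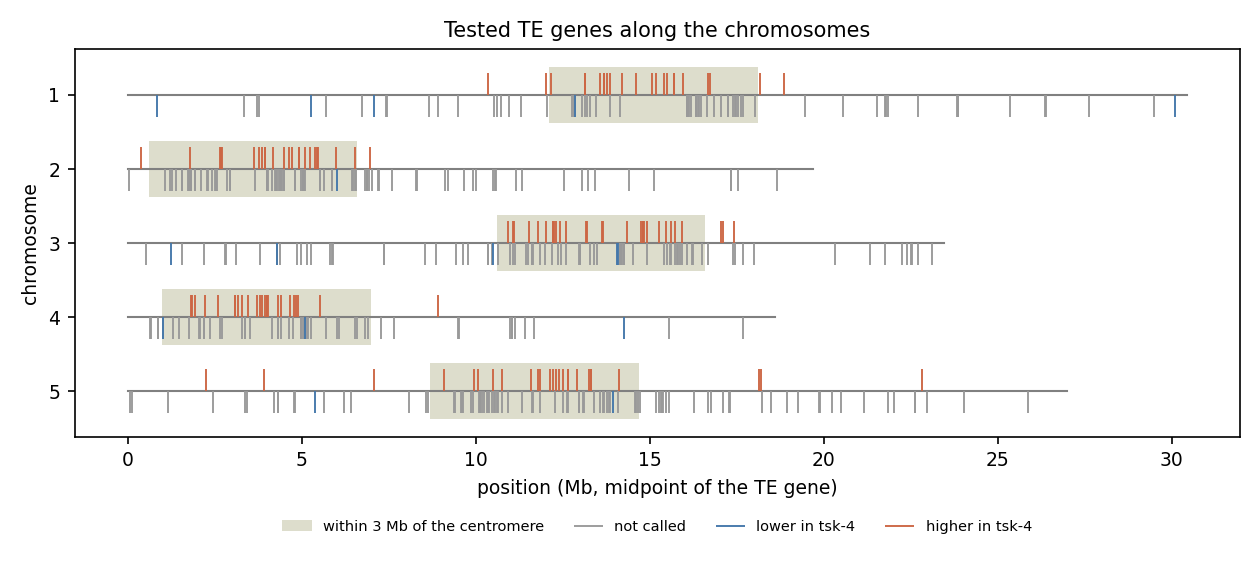
Positions in Mb of the 543 tested TE genes on the 5 chromosomes; orange marks were higher in tsk-4, blue lower and grey not called, and shading covers 3 Mb to each side of the centromere. Of the 128 higher calls 112 lie in the shaded regions, which hold 3254 of the 3901 annotated TE genes.

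Most TE genes called higher lay around the centromeres, as did most annotated TE genes. Within 3 Mb of a centromere were 112 of the 128 higher calls and 3254 of the 3901 annotated TE genes, so 3.44% were called higher there and 2.47% in the arms, an odds ratio of 1.41 (95% interval 0.822 to 2.56, Fisher exact p = 0.23), 1.37 with a window of 2 Mb and 2.59 (95% interval 1.07 to 8.16, Fisher exact p = 0.030) with 5 Mb. Among tested TE genes alone the odds ratio was 5.31, but the filter admits a TE gene silent in Col only if it has reads in all 3 tsk-4 libraries, and 113 of the 128 were of this kind, so silent elements that did not rise are missing from it. Among tested TE genes with a Col read 13 of 249 near centromeres and 2 of 181 in the arms were called higher, an odds ratio of 4.93 (95% interval 1.09 to 45.4, Fisher exact p = 0.030). Among TE genes without Col reads 20.6% near centromeres and 29.3% in the arms had a read in tsk-4. That odds ratio was 0.627 (95% interval 0.491 to 0.803, Fisher exact p = 0.00020). Of TE genes with reads in 1 genotype alone 83.5% and 65.5% had them in tsk-4. Here the odds ratio was 2.68 (95% interval 1.80 to 3.94, Fisher exact p = 6.2e-07). Neighbouring elements are not independent, and these comparisons point in different directions, so a preference for either region was not shown.

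TE fragments gave fewer and less stable calls. On average 2764 ± 6.93 fragments had a value above 0 in a Col library and 3221 ± 56.2 in a tsk-4 library (SD, n = 3; exact permutation p = 0.1, the smallest possible). Read numbers of fragments, with the floors and intervals made from them, rest on the smallest lengths that the values allow. AT1TE70815 had 0 reads in Col and 36 in tsk-4, at least 11.6-fold higher against a floor of 3 reads over the group. AT5TE44850 had 1 and 61, a ratio of 56.8 (95% counting interval 9.82 to 2279.5). AT2TE25295, AT1TE45385 and AT2TE32600 had 0 reads in Col and 15, 7 and 8 in tsk-4, and AT2TE54130, AT5TE96650 and AT1TE76910 had 5, 5 and 3 in Col and 0 in tsk-4. limma called 77 of 2509 fragments higher and 22 lower. With the filter applied again to 5 libraries it called 2, 1 and 9 higher and 1, 0 and 3 lower without Col 1, 2 and 3, and 0, 1 and 0 higher and 0, 3 and 0 lower without tsk-4 1, 2 and 3. At an unadjusted p under 0.05 there were 312, 303, 344, 235, 244 and 252 in that order. Recovered reads, with the inferred lengths, gave 89 higher and 47 lower, of which 42 and 9 were also calls on TPM. This test called 57 and 32 higher without Col 1 and Col 2, and 26, 23, 28 and 29 lower without Col 2, tsk-4 1, tsk-4 2 and tsk-4 3. Summed reads on fragments were 11264 ± 210.2 per 1000000 reads of the gene table in Col and 11149.7 ± 159 in tsk-4 (exact permutation p = 0.5), and 9577 ± 149 and 9961 ± 129 without the 5 most abundant fragments (exact permutation p = 0.1, the smallest possible).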

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

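Tests on recovered reads, positions over all annotated TE genes, the TE tables rescaled to the gene table and the leave-one-out counts on the features of the full test were chosen only after the results were seen. The lower level of TSK kept its direction and its call in every alternative that tested it, from -1.28 with a pseudocount of 1 to -2.08 on recovered reads and from -1.60 to -1.52 with a library left out; it fails the filter of 5 TPM. The odds ratio of 5.31 for higher TE genes near centromeres, 4.80 and 11.1 for windows of 2 and 5 Mb and 4.85 on recovered reads, came from tested TE genes only. Over all annotated TE genes it was 1.41 at 3 Mb and 1.37 at 2 Mb, no longer past the threshold, and 2.59 at 5 Mb (Fisher exact p = 0.030); for tested TE genes with a Col read it was 4.93 at 3 Mb. The difference in reads on TE genes, tsk-4 minus Col, stayed between 104 and 187 per 1000000 with a library left out. That in TE fragments was -114, lay between -215 and -5.11 with a library left out and turned to 384.6 without the 5 most abundant fragments, whose own fall sets the sign.

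Genes called higher and lower, 2912 and 971, became 1802 and 1607 with median-ratio scaling, 1704 and 1660 with quantile normalization and 445 and 121 at 2-fold or more; lower calls became 622 without the trend and 1954 on recovered reads. With the filter applied again, higher calls were 1802, 1927, 1783 and 3376 without Col 2, tsk-4 1, tsk-4 3 and Col 3, and lower calls 558, 501, 626 and 578 without Col 1, Col 2, tsk-4 2 and tsk-4 3; on the features of the full test they ranged from 1798 to 3364 and from 507 to 1170. TE genes, 128 and 16, became 57 and 36 with quantile normalization, whose equal distributions lower other TE genes in tsk-4 by construction. Lower calls of TE genes became 10 with the replicate block, 4 without the trend, 6 in the rescaled table and 4 at 2-fold or more. With the filter applied again limma called 0, 3 and 0 higher and 0, 1 and 0 lower without tsk-4 1, 2 and 3 (54, 53 and 56 at an unadjusted p under 0.05) and 8 lower without Col 2, with up to 142 higher without Col 3; on the features of the full test the ranges were 117 to 141 and 10 to 25. TE fragments, 77 and 22, became 7 and 5 with no filter, 32 and 12 at a mean of 5 TPM and 0 and 0 with the replicate block in limma (299 at an unadjusted p under 0.05); lower calls became 47 on recovered reads. With a library left out they ranged from 0 to 25 and from 0 to 10 on the features of the full test, and with the filter applied again were 2, 1, 9, 0, 1 and 0 higher and 1, 0, 3, 0, 3 and 0 lower without Col 1, 2 and 3 and tsk-4 1, 2 and 3. The changes of filter and the 2-fold minimum alter which features can be called.

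The replicate numbers did not pair the samples: over genes, same-numbered libraries correlated at 0.115, -0.087 and -0.109 in their deviations from the group means. The highest correlation, 0.248, was between Col 3 and tsk-4 2. On the second principal component, with 16.5% of the variance, only these libraries lay below 0, at -27.4 and -16.2. UF3GT, DFR, LDOX and PAP1 were each highest in these libraries within their genotype. With the replicate block limma called 2310 genes higher and 750 lower and 123 TE genes higher, besides the counts above.

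Of 72 named features other than TSK that were called, 55 to 67 kept their call with a library left out, 68 with median-ratio scaling, 66 with quantile normalization, 59 with the replicate block and 59 of the 64 testable on recovered reads, and 0 changed sign. Of those not called, QQS went from 0.07 to -0.00782 with median-ratio scaling, -0.0185 with quantile normalization and -0.0137 on recovered reads, and ranged from -0.118 to 0.205 with a library left out. CRA1 went from 0.01 to -0.0842, -0.0998 and -0.0686 in these settings and ranged from -0.454 to 0.499, below 0 without Col 3, tsk-4 1 and tsk-4 3. HSP90.1 ranged from -0.0147 to 0.401, lowest without Col 3. Of the 5 lists called by camera 0 kept the call with an estimated correlation, 4 with fry and 4 with quantile normalization, without a change of direction. Of the others, adjusted p-values signed by direction were 0.654 for DNA replication and 0.489 for PRC2 with fry, 0.735 for seed markers on recovered reads and -0.946 for abscisic acid and cold with the replicate block, each against the direction of camera on TPM. With a library left out root markers ranged from -0.999 to 0.956 and abscisic acid and cold from -0.796 to 0.879.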

Other observations

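The tests of depth, of TE genes and genes used once, of gaps without AT3G46340, of an even spread of genomic DNA and of other divisions of the libraries, and the grouping of genes by symbol, were chosen only after the results were seen. Grouped by the prefix of their symbol, 128 families were compared with camera. In the SAUR group of auxin-responsive genes 2 of 14 fell and 0 rose (median -0.28), and in the KCS group of fatty acid elongation 6 of 17 fell and 2 rose (median -0.24), with camera adjusted p = 0.040 and 0.050. With an estimated correlation the adjusted p of each of these 2 families was 0.89. Of 12 tested TE genes noted as Sadhu elements, non-coding retroelements, 1 was higher, SADHU3-2, with 10 reads in Col and 142 in tsk-4, and 1 was lower.

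More TE genes had reads in tsk-4 than in Col. After thinning to equal depth the tsk-4 libraries still had 311.3 more TE genes with a read on average, without overlap between the genotypes. This argues against depth. Of the TE genes called higher 4.69% (95% exact interval 1.74 to 9.92) lay within 1 kb of a gene called higher. For most of these TE genes that argues against transcription running in from genes within 1 kb that rose. For the few beside such a gene it stays open. Genomic DNA in the tsk-4 libraries stays open. Among features without Col reads, TE genes had 1.102 to 1.289 times the reads per kb of protein-coding genes. These ratios lie between the limits of 1 and 2 set for either answer. Reads in tsk-4 alone were found for 736 protein-coding genes and 696 TE genes, against 452 and 174 in Col alone. An even spread of DNA predicts 1.41 TE genes with at least 20 reads where 22 were seen, so an even spread does not account for those 22. An uneven spread of DNA over repeats was not tested, so DNA is not excluded for them either. Of the 696 elements 492 had at most 3 reads. Reads shared between TE copies were not tested, and a loss of silencing in tsk-4 may be the source but stays among the open explanations.

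Most gene calls were higher in tsk-4 on the deposited scale. The 100 most abundant genes took 34.0 ± 0.730% of the TPM in Col and 29.6 ± 0.286% in tsk-4 (SD, n = 3). Without them and with the rest rescaled, 54.8% of the calls were higher. A candidate explanation for the excess of higher calls is therefore the fall of abundant transcripts, which raises the TPM of the others. Total RNA per cell was not measured here, so a wider rise stays open.

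AT3G46340, the gene with the largest rise, lies 592 bp from AT3G46345, a TE gene with 0 reads in Col and 3 in tsk-4, which prompted the hypothesis that genes near TE genes that rose also rise. Of 25 tested genes within 2 kb of a TE gene called higher 11 were called higher (44.0%), against 119 of 728 within 2 kb of other TE genes (16.3%), an odds ratio of 4.01 (95% interval 1.61 to 9.77, two-sided Fisher exact p = 0.0014), or 3.65 without AT3G46340 (Fisher exact p = 0.0036). Several of these genes share a TE gene; with each TE gene and gene used once and without AT3G46340 the odds ratio was 3.46 (interval 1.18 to 9.72). At gaps of 500 bp to 2 kb with AT3G46340, the version written before the test, it was 3.36 (interval 1.15 to 9.29, Fisher exact p = 0.013). With each used once that was 3.25 (1.02 to 9.80). AT3G46340 had prompted the comparison. Without it the odds ratio at these gaps was 2.94 (interval 0.952 to 8.41, Fisher exact p = 0.031), or 2.79 (0.809 to 8.76) with each used once. Whether the interval at these gaps excludes no difference, the condition written before the test, thus depends on that gene. Reads that run across adjacent features stay open. Shared activation of genes and neighbouring TE genes may also account for the excess; its direction, and a wider effect of the chromosomal region, were not tested.

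The 6 libraries can be divided into 3 and 3 in 10 ways. The real division called 3883 genes, 144 TE genes and 99 TE fragments, and the highest count from limma in the other divisions was 0, 0 and 8, with 246 to 1216, 15 to 20 and 91 to 149 at an unadjusted p under 0.05. The real division alone called as many in each of the 3 tables, and with 10 divisions a share under 0.05 cannot be reached.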
